A study of Mus musculus with 2 samples.

How the data were processed

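Single-cell 3′ RNA was measured in CD4+ T cells from the spleens of C57BL/6 mice infected with LCMV Cl13, the clone 13 strain of lymphocytic choriomeningitis virus. The sorted cells recognised the viral GP66 epitope and expressed a red fluorescent reporter of Il21 (tRFP). There was 1 library for day 7 and 1 for day 14 after infection. Cells of 2 donor mice went into each, and the counts of the 2 mice cannot be told apart. The authors' deposited matrices hold raw UMI counts per gene and cell barcode (a UMI is a tag that marks 1 captured RNA molecule), with no normalisation. Per the submitters' processing notes they were made with Cell Ranger on the mm10 genome. The Cell Ranger version, the aligner settings and the rule by which barcodes were called cells are not given in the sources used here. The matrices list 27998 genes. Near-identical gene copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, the Hist1h2 and Serpina3 families) are hard to separate with short 3′ reads, so their single values are uncertain.

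A barcode was kept with at least 500 genes and at most 10% mitochondrial UMIs. This left out 11 of 293 barcodes on day 7 (2 for few genes, 9 for mitochondrial UMIs) and 44 of 604 on day 14 (12 and 32). Scrublet, run per library through scanpy, called 8 cells on day 7 and 13 on day 14 as likely doublets, and these were kept. UMIs were summed over the kept cells of a library and scaled to CPM (the UMIs of a gene per 1000000 UMIs). Genes with a mean CPM of at least 10 over the libraries were compared as log2 of day 14 over day 7. A gene with 0 UMIs in a sum was set to a floor of 3 counts per sum, which is 0.736 CPM on day 7 and 0.838 CPM on day 14 over all cells. Intervals are 95% and exact (conditional binomial for ratios, Poisson for CPM, Clopper-Pearson for shares). For a list median the interval comes from 1000 Poisson redraws of its counts. They cover counting error only. With 1 library per day there is no replicate, so no test between days, no p and no standard error could be had. At least 2-fold is a size class and not a test, and cells are not replicates.

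Gene lists were fixed before the data were examined. For each list the median log2 ratio of the measured members was placed among 10000 random lists matched on mean expression in 25 bins, and members at least 1.5-fold higher or lower were counted. Named genes followed a rule fixed at the same time. Over all cells it took the 12 highest and 12 lowest ratios among genes with a mean CPM of at least 50, and within each class the 6 highest and 6 lowest. For cells with against without an Il21 UMI it took the 8 most higher and 8 most lower in both libraries, among genes with at least 40 UMIs. The rule left out ribosomal, mitochondrial, antigen receptor and sex-linked genes and unnamed transcripts. It added 2 to 4 list members with the largest ratios and a fixed set of T cell genes (Il21, Cxcr5, Bcl6, Pdcd1, Tcf7, Tbx21, Cxcr6, Ifng, Il10, Ccr7, Tox, Lag3, Mki67). Malat1, S1pr1, Klf2, Lgals1, Rtp4, Hsp90ab1 and C1qc fall outside this rule and were chosen after their values were seen, as was the use of the rule in T cell clusters. Some genes that the rule or the lists name are not reported here.

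For clustering, counts were scaled to 10000 per cell and log transformed. Both libraries were clustered together on 2000 variable genes, 20 principal components and 15 neighbours at a Leiden resolution of 0.8. A cluster took the class whose marker list had most genes among its 20 genes highest over the other cells, with at least 2 there and at least 3 detected in 20% of its cells. Days were compared within a class only with at least 30 cells in each library. For shares of cells with an Il21 UMI and for cell cycle counts, every cell was thinned at random to 2000 UMIs. The pipeline was tested on simulated data: 45 of 48 genes simulated at 2.5-fold and 2 of 7056 unchanged genes came out at least 2-fold different, 95.4% of the counting intervals held the true ratio, and all 842 simulated cells got their class back. Those cells came from summed profiles of 5 clusters without a library difference, so their recovery does not test the real classes. The simulated gene counts held Poisson counting error only. The gene and interval results therefore check the calculation and say nothing of variation between cells, mice or libraries.

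Alternatives tried were other cell filters, doublet removal, edgeR TMM and DESeq2 scaling factors (no edgeR or DESeq2 test was run), per-cell means, thinning, other expression filters, other clusterings and other Il21 and cell cycle depths. Several were added after the data were seen, among them leaving out clusters led by genes of other cell types, scaling within a class, and clustering at matched depth. T cell antigen receptor segments are absent from the gene names of the matrices, so the planned count of segment use gave no value. Igkc, Ighm, Ighd, Trac, Trbc2 and Cd244a are absent as well. Positions are from the GENCODE vM21 annotation of mm10 (GRCm38). Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.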

Results

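The day 7 library held 282 cells after filtering, with 4077477 UMIs and a median of 11833 UMIs and 2918.5 genes per cell. The day 14 library held 560 cells, with 3578098 UMIs and a median of 5767.5 UMIs and 1889.5 genes. Mitochondrial transcripts took a median of 2.99% and 3.51% of a cell's UMIs. Ratios are of day 14 over day 7, and brackets give 95% intervals that cover counting error only. Each day is 1 library, so a difference between days cannot be separated from a difference between libraries.

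The first question was how much Il21, the cytokine gene behind the sort, the sorted cells carried at each time. Il21 (ENSMUSG00000027718, protein coding, chromosome 3, 37222759 to 37232636, minus strand) had 221 UMIs on day 7 and 239 on day 14 over all cells, a log2 ratio of 0.30 (0.03 to 0.57). With TMM factors it was 0.20 (-0.07 to 0.47), with DESeq2 factors 0.16 (-0.11 to 0.43) and under a stricter cell filter 0.06 (-0.25 to 0.36), so a difference over all cells was not detectable under these choices. In clusters of T cells it was 51.8 CPM (44.6 to 59.9) on day 7 and 72.6 CPM (63.2 to 83.0) on day 14, a log2 ratio of 0.49 (0.20 to 0.78), and 0.23 (-0.09 to 0.56) under the stricter filter. With the T cells of a mixed haemoglobin-led cluster put back the ratio was 0.43 (0.16 to 0.71). T follicular helper (Tfh) cells help B cells in germinal centres. In cells with Tfh markers Il21 was 71.4 CPM (59.0 to 85.6) on day 7 and 124 CPM (102 to 151) on day 14. It was lower in cells with T helper 1 (Th1) markers, at 39.3 CPM (27.7 to 54.2) and 41.9 CPM (28.0 to 60.1). Levels in the other classes are not compared here. Il21 is itself on the marker list by which clusters were named Tfh-like, so these levels are not independent of the class names. Tfh-like clusters held 52.5% of the Il21 UMIs on day 7 and 44.4% on day 14, and central-memory-like cells held 2.26% and 30.1%. Th1-like cells held 16.7% and 12.1%, and clusters led by genes of other cell types 17.2% and 10.9%. With every cell thinned to 2000 UMIs, 27 of 282 cells (9.57%, 6.4 to 13.6) had an Il21 UMI on day 7 and 64 of 548 (11.7%, 9.11 to 14.7) on day 14, where 12 shallow cells were left out. At 3000 UMIs day 7 was the higher, at 17.5% (13.2 to 22.5) and 16.4% (13.3 to 19.9), but the intervals overlapped there as at 2000 UMIs. At full depth the shares were 39.7% and 25.7%, where day 7 cells were the deeper. Red cells and neutrophils, which should lack Il21, were the background. Among them 1 of 25 thinned day 14 cells had an Il21 UMI (4%, 0.101 to 20.4) and 0 of 4 on day 7, where the floor of 3 counts allows up to 75% and the exact interval up to 60.2%, with medians of 12566 and 8315.5 UMIs before thinning. T cell clusters gave 12.4% (9.61 to 15.7) and 8.49% (5.40 to 12.6) at the same thinning, with medians of 5660 and 11584 UMIs, so these shares lie within the interval of the background. That interval is wide because it rests on few cells. Without thinning, 27 day 14 red cells and neutrophils held 3 Il21 UMIs, and 11.1% (2.35 to 29.2) of these cells had one. The 493 day 14 cells of T cell clusters held 213, and 26.2% (22.3 to 30.3) had one. These intervals still overlap, although the background cells were the deeper. On day 14 the thinned share was 21.4% (14.7 to 29.4) in Tfh-like and 6.67% (2.92 to 12.7) in Th1-like cells, a difference between classes beyond their counting intervals. On day 7 it was 12.7% (7.69 to 19.3) and 4.41% (0.919 to 12.4), where the intervals overlap. Since Il21 is on the list that names Tfh-like clusters, these shares are not independent of the class on either day.

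**Figure D1:**
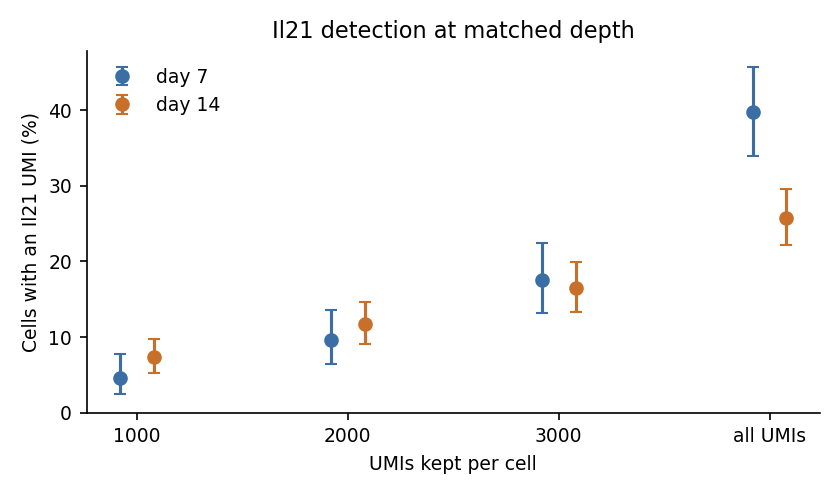
Share of cells with at least 1 Il21 UMI (vertical axis, %) against the UMIs kept per cell (horizontal axis), for day 7 (blue) and day 14 (orange), with exact 95% intervals. At 2000 UMIs the shares are 9.57% and 11.7%, and with all UMIs, where depth is not matched, 39.7% and 25.7%.

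The second comparison asked which genes differed between the days. Over all cells, genes of red cells and neutrophils led the higher side. This rested on few cells for the red cell list: of 38129 day 14 Hba-a1 UMIs, 37171 were in 18 cells with at least 100 red cell UMIs. The list's median of 3.71 turned to -0.91 with cells above 2 times their own library's median UMIs left out. Day 14 cells had fewer UMIs, so this cut fell at a lower depth there, and the change of sign may come from the unequal cut. Hba-a1, a haemoglobin chain, was 13.7-fold higher on day 14, Alas2, the first enzyme of haem synthesis in red cells, was 18.7-fold higher, and Car2, a carbonic anhydrase of red cells, was 189-fold higher. Camp, an antimicrobial peptide of neutrophils, had 0 UMIs on day 7 and 2265 on day 14 (at least 860-fold higher against the floor of 3 counts), and Ltf, lactoferrin, was at least 148-fold higher against it. Their counting intervals begin at log2 ratios of 9.45 for Camp and 6.90 for Ltf. Ngp (153-fold) and Chil3 (40-fold), also made by neutrophils and other myeloid cells, and Apoe, an apolipoprotein of macrophages (16.8-fold), were higher as well, as were Blvrb (14.3-fold), Apol11b (13.1-fold), Hbb-bt (12.5-fold) and Ctse (28.2-fold). Of the 767 day 14 Ctse UMIs, 539 were in T cell clusters and 185 in red cells. The lower side included Ccl3 and Ccl4, chemokines of activated T cells, which were 7.70-fold and 4.04-fold higher on day 7. Also higher on day 7 were Nrgn (4.62-fold), Ifitm1 (4.52-fold), Ddit4 (4.39-fold), Phgdh, the first enzyme of serine synthesis (3.54-fold), Nme2 (3.53-fold), AY036118 (3.48-fold), Serpinb9, an inhibitor of granzyme B (3.18-fold), and Serpinb6b (3.15-fold). The glycolytic enzymes Tpi1 and Ldha were each 3.09-fold higher on day 7. Of 7256 genes compared, 369 were at least 2-fold higher and 226 at least 2-fold lower on day 14, where counting noise alone gave 1 and 0.85. Which side was larger depended on scaling: TMM factors gave 271 higher and 308 lower and DESeq2 factors 245 and 352, since they moved the median of all genes from 0.03 to -0.07 and -0.11.

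Clusters led by genes of other cell types held 23 cells on day 7 and 67 on day 14, so genes were also compared over the remaining T cell clusters (259 and 493 cells), a set chosen after the data were seen. Genes of resting and recirculating T cells were higher on day 14. Il7r, the receptor of the survival cytokine IL-7 (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand), went from 21.2 to 98.8 CPM, a log2 ratio of 2.22 (1.85 to 2.61), and Ccr7, the lymph node homing receptor (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, minus strand), from 15.3 to 29.3 CPM, a log2 ratio of 0.94 (0.43 to 1.46). Bcl2, which protects from cell death (1.13), Gpr183 (0.92), S1pr1 (0.86), which lets T cells leave lymphoid tissue, and the transcription factor Tcf7 (0.61) were higher too. Of 12 measured central-memory genes 8 were at least 1.5-fold higher and 0 lower, with a median of 0.80 (0.63 to 0.86), above 100% of random lists. Within Tfh-like cells the median was 0.30 (0.10 to 0.41, and 0.05 with TMM factors), and within Th1-like cells -0.006 (-0.35 to 0.36). Among chemokines and migration receptors 10 of 20 were at least 1.5-fold higher and 2 lower (median 0.57, 0.35 to 0.63), and the median was 0.19 to 0.46 under the alternatives. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand) was at a log2 ratio of 1.61 (1.57 to 1.64) and the chemokine receptor Ccr2 at 1.81, while Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355, minus strand) was at -2.66 (-2.83 to -2.49) and Ccl4 at -1.75. The 342 genes at least 2-fold higher and 223 lower among 7179 became 233 and 308 with TMM and 197 and 348 with DESeq2 factors, as the median of all genes moved from 0.07 to -0.05 and -0.09.

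Genes of proliferation and of sugar metabolism were lower on day 14 in the T cell clusters. Of 16 glycolysis genes 12 were at least 1.5-fold lower and 0 higher, with a median of -0.85 (-0.96 to -0.82), below all random lists drawn. Tpi1 (ENSMUSG00000023456, chromosome 6, 124810586 to 124814296, minus strand) was at -1.53 (-1.70 to -1.36), Ldha, lactate dehydrogenase, at -1.46 (-1.57 to -1.36), and the lactate exporter Slc16a3 at -1.62 (-2.35 to -0.94). Of 41 G2/M genes 32 were lower and 0 higher (median -1.15, -1.22 to -1), with Birc5 at -2.22, Cdk1 at -2.21, Ube2c at -2.14, Ccnb2 at -2.01 and Cdca3 at -1.82, all acting in mitosis, and Mki67 at -0.91. Of 35 S phase genes 22 were lower and 0 higher (median -0.91, -1 to -0.70), with Rrm2, a subunit of the enzyme that makes DNA building blocks, at -2.43. Much of this rested on the cycling cluster of 33 and 14 cells: without it the G2/M median in T cell clusters was -0.38 and the S phase median -0.30. Hist1h2ap, a histone gene, was at -2.08 and Stmn1 at -1.91. Nrgn was at -2.10 and Ddit4, an inhibitor of the growth kinase mTOR, at -2.09. Proteasome genes had a median of -0.55 (-0.60 to -0.47, 19 of 42 lower) and nuclear-encoded oxidative phosphorylation genes of -0.39 (-0.42 to -0.34, 13 of 78 lower). Cytosolic ribosomal protein genes stayed close to 0 (median -0.05, -0.06 to -0.03). The nuclear RNA Malat1, whose share depends on RNA quality, was at 0.92 (0.91 to 0.93), and mitochondrially encoded genes had a median of 0.24 (0.19 to 0.28). That median was 0.12 with TMM factors, 0.08 with DESeq2 factors and 0.09 under the stricter cell filter.

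Among the helper lists in T cell clusters, the Th1 list had a median of -0.25 (-0.31 to -0.17), with 6 of 21 genes lower and 4 higher. That median lay within the range of random lists (-0.29 to 0.18) and was -0.41 with DESeq2 factors and -0.04 with cells thinned to 2000 UMIs. Gzmb, a cytotoxic protease, was at -1.40 (-1.54 to -1.26) and Lgals1 at -1.28, while Id2 was at 1.06. Tbx21, the Th1 master regulator, was at -0.41 (-0.79 to -0.03) and Ifng at -0.20 (-0.31 to -0.08). The Tfh list had a median of 0.09 (0.01 to 0.22), which turned to -0.03 and -0.07 with TMM and DESeq2 factors. Differences in Cxcr5, the follicle homing receptor (0.03, -0.36 to 0.40), in Bcl6, the Tfh master regulator (0.09, -0.48 to 0.65), and in Cxcr6 (0.13, -0.05 to 0.31) were not detectable at this depth. The inhibitory receptor list went both ways, with 3 of 12 genes higher and 4 lower: Pdcd1, which encodes PD-1, was at -0.74 (-0.90 to -0.58), Lag3 at -0.26 (-0.38 to -0.14) and Cd160 at -2.26, while Tox, a transcription factor of chronically stimulated T cells, was at 0.64 (0.51 to 0.76). Il10, an anti-inflammatory cytokine, was at 1.26 (0.92 to 1.61) and Ltb at 1.14, and the cytokine list at a median of 0.35 (0.18 to 0.54), which was 0.06 to 0.63 under the alternatives.

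Among genes with a mean of at least 50 CPM that the naming rule covers, Ifitm1 was the lowest and Ctse the highest in T cell clusters. Ifitm1, an interferon-induced membrane protein (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825, plus strand), had 574 UMIs on day 7 and 8 on day 14, a log2 ratio of -5.90 (-7.12 to -4.91). In clusters led by other cell types it was 101 CPM on day 7 and 177 CPM on day 14. Ctse, the protease cathepsin E (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505, plus strand), went from 8.21 to 184 CPM, a log2 ratio of 4.48 (3.95 to 5.08), and 26 of 259 T cells (10.0%) on day 7 and 289 of 493 (58.6%) on day 14 had a UMI. Ramp1 (2.77), Serpina3g (2.06), PISD (2.00) and Zbtb20 (1.91) were higher as well. RNA of other cells was also higher in these T cells: Hbb-bt was at 4.22, Hba-a1 at 3.95, Hba-a2 at 3.59, Hbb-bs at 3.27, S100a9 at 3.08 and S100a8 at 2.78, and below 50 CPM the macrophage gene Apoe, with 6 and 184 UMIs, at 5.21 (4.06 to 6.67).

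**Figure D2:**
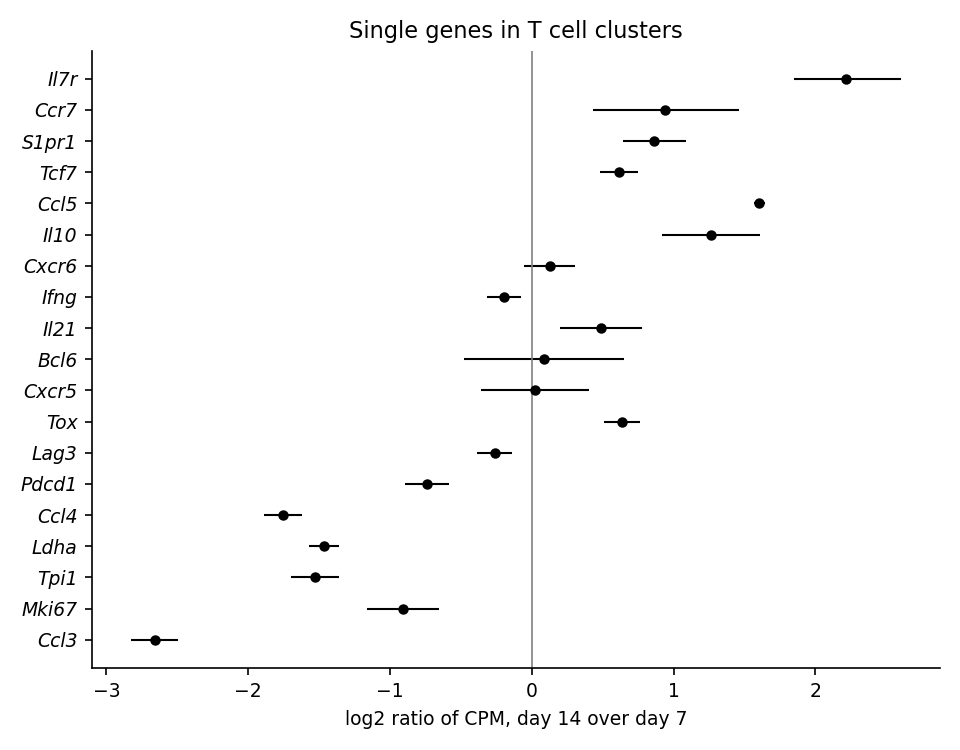
Log2 ratio of CPM, day 14 over day 7 (horizontal axis), of single genes (vertical axis) in T cell clusters (259 and 493 cells); points are ratios and lines exact 95% counting intervals. Il7r lies at 2.22 and Ccl5 at 1.61, Ldha at -1.46 and Ccl3 at -2.66, and the intervals of Cxcr5, Bcl6 and Cxcr6 include 0.

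**Figure D3:**
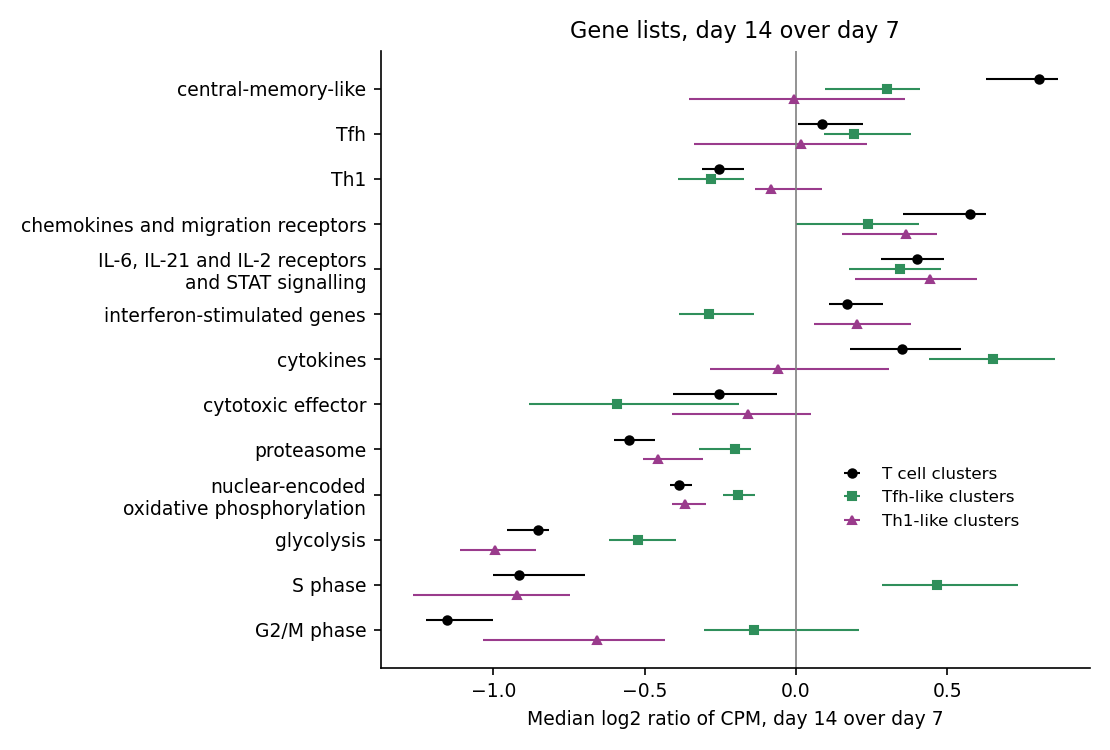
Median log2 ratio of CPM, day 14 over day 7 (horizontal axis), of gene lists (vertical axis) in T cell clusters (black circles), Tfh-like clusters (green squares) and Th1-like clusters (purple triangles), with 95% counting intervals as lines. Glycolysis lies below 0 in all 3 sets (-0.85, -0.52 and -0.99), and the central-memory list is at 0.80, 0.30 and -0.006. The Tfh and chemokine medians of Tfh-like clusters and the Tfh medians of T cell and Th1-like clusters fall below 0 with TMM or DESeq2 factors.

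The third comparison asked which kinds of cells made up each library. Tfh-like cells were 142 of 282 on day 7 (50.4%, 44.4 to 56.3) and 133 of 560 on day 14 (23.8%, 20.3 to 27.5). Central-memory-like cells, in a cluster marked by Ccr7, Il7r, Klf2 and S1pr1, were 16 of 282 (5.67%, 3.28 to 9.05) and 222 of 560 (39.6%, 35.6 to 43.8). Th1-like cells were 24.1% (19.2 to 29.5) and 22.1% (18.8 to 25.8), and cycling cells 11.7% (8.19 to 16) and 2.5% (1.37 to 4.16). Clusters led by other cell types were 8.16% (5.24 to 12) and 12% (9.39 to 14.9). The largest of these, led by haemoglobin genes, was mixed: 15 of its 19 day 7 cells and 7 of its 32 day 14 cells had at least 10 UMIs of Cd3 and Cd4 genes, while 1 and 17 had at least 100 red cell UMIs. The same marker genes also differed in sums over each library, though the central-memory median was 0.30 in Tfh-like and -0.006 in Th1-like cells. Most clusters came mainly from 1 library, so a cluster may stand for its library as much as for a cell type. The shares depended on the clustering: with each library clustered alone, central-memory-like cells were 23.8% on day 7 and 22.5% on day 14, and Tfh-like cells 17.7% and 32.0%. That setting also named 33.0% of day 7 cells as other cell types and 0% as Th1-like, so its classes are not those of the joint clustering. Resolution 1.2 gave Tfh-like shares of 20.6% and 30.2%, with 67 cells left without a class and 48 in interferon-stimulated clusters. Cycling cells were 18.8% and 8.39% at resolution 0.4 and 25.5% on day 7 with libraries clustered alone, and other cell types 1.06% and 1.96% at resolution 0.4.

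**Figure D4:**
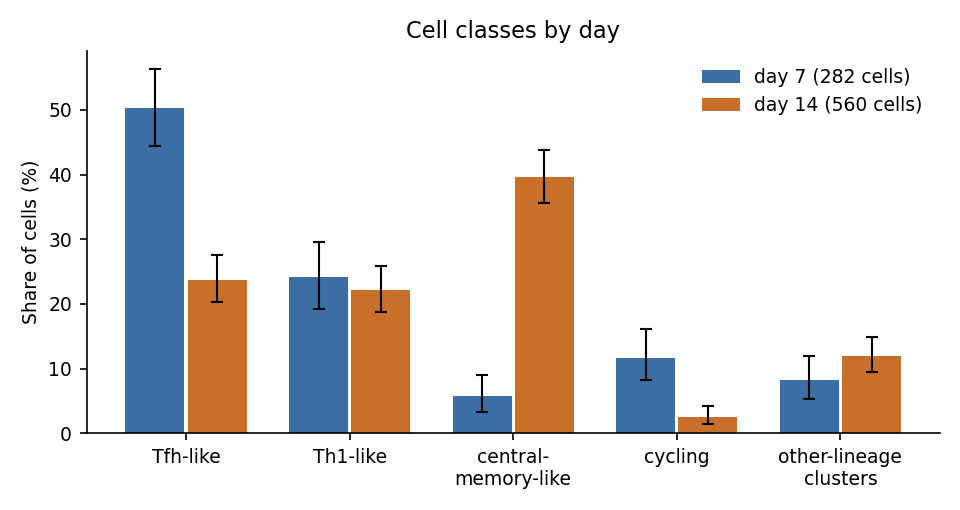
Share of cells (vertical axis, %) in each class (horizontal axis) for day 7 (blue, 282 cells) and day 14 (orange, 560 cells), with exact 95% intervals, from clustering both libraries together. Tfh-like cells are 50.4% and 23.8% and central-memory-like cells 5.67% and 39.6%, differences that were lost or turned with each library clustered alone, where 33.0% of day 7 cells were named as other cell types.

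The fourth comparison held the class name fixed, though each class joined clusters that differed in their share of day 7 and day 14 cells. Among Tfh-like cells (142 and 133), cytokine genes and some genes of T cell signalling were higher on day 14. The early genes Nr4a1 (1.52, 1.07 to 1.97), Egr2 (1.30) and Egr1 (1.09), switched on by antigen receptor signalling, Il21 (0.80, 0.41 to 1.2), Tnfsf11 (1.06), Il2 (1.12), Il7r (1.26) and Ccl5 (2.15, 1.96 to 2.35) were higher, and 9 of 14 cytokine genes were at least 1.5-fold higher and 1 lower (median 0.65, 0.44 to 0.85, and 0.40 with TMM factors). Of 19 genes induced by the antigen receptor 5 were at least 1.5-fold higher and 13 within 1.5-fold (median 0.36, 0.17 to 0.52, and 0.11 with TMM factors). The stress list was at 0.36 (0.19 to 0.52) as well. The interferon-stimulated list was lower, with 9 of 36 genes lower and 2 higher (median -0.29, -0.39 to -0.14, and -0.54 with TMM factors). Ifit3 was at -0.96 and Rtp4 at -0.80. Glycolysis had a median of -0.52 (-0.62 to -0.40, and -0.77 with TMM factors), with 4 of 15 genes lower, and Ldha at -0.93. AY036118 (-1.96), Ddit4 (-1.94), the centromere histone Cenpa (-1.66), Cd160 (-1.21) and Nrgn (-1.2) were among the lowest genes under the naming rule. The highest were Apoe (5.41, 4 to 7.32, from 4 and 89 UMIs), Ctse (4.26), Hbb-bt (4.03), Hba-a1 (3.29), Hba-a2 (3.04) and Hbb-bs (2.98), and Malat1 was at 0.64. Red cell and macrophage RNA was thus higher in these cells too. Ccl5 had a UMI in 99.2% of the cells of a mainly day 14 Th1-like cluster. Whether the Ccl5 ratio of Tfh-like cells includes RNA from such cells was not tested. Of 7071 genes 548 were at least 2-fold higher and 134 lower, where counting noise alone gave 69.5 and 82.0, and with TMM factors 266 and 271, as the median of all genes moved from 0.19 to -0.07. The Tfh list moved with it, from 0.19 to -0.06, and the chemokine list from 0.24 to -0.01. Of the Tfh-like clusters 1 held 85 day 7 and 5 day 14 cells and another 8 and 73, and in the cluster that held 49 and 55 cells the glycolysis median was -0.38 (-0.49 to -0.13) and the cytokine median 0.53 (0.21 to 0.91). The intervals there included 0 for antigen receptor induced genes (0.19, -0.04 to 0.47) and interferon-stimulated genes (-0.13, -0.31 to 0.11). Egr2 and Tnfsf11 are among the genes that most mark the mainly day 14 cluster, and Cd160, Ddit4 and Nrgn the mainly day 7 cluster. The ratios of these genes are therefore not independent of the clustering.

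Among Th1-like cells (68 and 124), effector chemokines differed in both directions. Ccl5 was at 1.99 (1.94 to 2.03), and the receptors Ccr2 (2.47), Cx3cr1, a marker of terminal effector cells (2.03, 1.16 to 2.98), and Cxcr6 (0.57, 0.37 to 0.77) were higher on day 14. Ccl3 was at -2.51 (-2.70 to -2.33) and Ccl4 at -1.60 (-1.75 to -1.46). Il10 went from 47.8 to 206 CPM (2.11, 1.62 to 2.63), and Maf, a transcription factor that drives Il10, was at 1.54 (1.30 to 1.78). Ifitm1 had 525 UMIs on day 7 and 3 on day 14 (-7.01, -9.29 to -5.45). Gzmb (-0.96), Pdcd1 (-0.56) and Lag3 (-0.42) were lower, and so were Nrgn (-3.25), the actin-capping gene Capg (-2.44), Stmn1 (-2.41) and Ddit4 (-2.17). Glycolysis had 12 of 16 genes lower and 0 higher (median -0.99, -1.11 to -0.86), and S phase 26 of 36 lower and 2 higher (median -0.92, -1.27 to -0.75). Of the genes induced by the antigen receptor 0 of 17 were higher and 6 lower (median -0.30, -0.56 to 0.01). That interval included 0, and the median lay within the range of random lists (-0.32 to 0.33). The difference from Tfh-like cells was not tested. The Th1 list itself was at -0.08 (-0.13 to 0.08), with 5 genes higher and 6 lower of 21. Ctse (4.22), Hba-a1 (4.05), Hbb-bt (3.80), Hba-a2 (3.64), Hbb-bs (3.29) and S100a9 (3.19) were the highest genes with a mean of at least 50 CPM, and Malat1 was at 1.2. Of 7066 genes 553 were at least 2-fold higher and 427 lower, where counting noise alone gave 127 and 134. Day 7 Th1-like cells were 66 cells of a cluster with 6 day 14 cells, and day 14 ones 118 cells of a cluster with 2 day 7 cells. Ccl3, Ccl4 and Gzmb are among the genes that most mark the mainly day 7 cluster, and Ccl5, Cxcr6, Il10, Ccr2 and Cx3cr1 the mainly day 14 cluster. The ratios of these genes are therefore not independent of the clustering.

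The fifth comparison set cells with an Il21 UMI against cells without within each library, at 2000 UMIs per cell. Genes of follicular helper cells were higher in cells with Il21. Cd200, a surface protein of Tfh cells, was higher by a log2 ratio of 1.33 (0.80 to 1.83) on day 7 and 0.91 (0.42 to 1.37) on day 14, Ctsz by 1.15 (0.11 to 2.08) and 1.02 (0.09 to 1.86), and Trim8 by 1.36 (0.12 to 2.46) and 0.72 (0.02 to 1.37). Sipa1, Gata3, Skp1a, Mrps6 and Btla, an inhibitory receptor of Tfh cells, had ratios above 0 in both libraries, but the interval included 0 on day 7 for Sipa1, Gata3 and Btla, on day 14 for Skp1a, and on both days for Mrps6. The pooled Tfh list was at 0.64 (0.44 to 0.84) and 0.41 (0.27 to 0.55), though at 1000 UMIs per cell its day 7 value was 0.08 (-0.40 to 0.53), and the pooled Th1 list at -0.76 (-0.89 to -0.63) and -0.94 (-1.03 to -0.86). The lowest genes in cells with Il21 were those of neutrophils and red cells (S100a8 at -5.47 and -4.19, S100a9, Retnlg, Hba-a1, Hba-a2, Hbb-bt and Hbb-bs) and Ifitm3. Within Tfh-like cells alone the Tfh list was at 0.31 (0.08 to 0.54) on day 7 and at -0.12 (-0.31 to 0.08) on day 14.

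The sixth comparison was of the cell cycle. G2/M genes took 0.363% of thinned UMIs on day 7 and 0.229% on day 14, and S phase genes 0.188% and 0.127%. Cells with at least 3 G2/M UMIs were 65.2% (59.4 to 70.8) and 55.8% (51.6 to 60.0), and with at least 5 they were 39.4% (33.6 to 45.3) and 22.1% (18.7 to 25.8). Red cells and neutrophils, some of whose precursors divide, gave 64.0% (42.5 to 82.0, n = 25) on day 14 and 50% (n = 4) on day 7 at 3 UMIs, so that share does not separate cycling cells from background. In the cycling cluster, 33 cells on day 7 and 14 on day 14, G2/M genes took 1.60% and 2.10% of UMIs.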

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

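The differences between classes were looked at only after the list medians were known, and none of them was tested. S phase genes were on opposite sides in Tfh-like cells (0.47) and Th1-like cells (-0.92), a difference of 1.39 on the log2 scale. The Tfh-like value lay within the range of random lists matched on expression (-0.00458 to 0.51), was 0.21 with TMM factors, and was 0.23 (-0.09 to 0.58) in the Tfh-like cluster shared by both days. Interferon-stimulated genes were at -0.29 in Tfh-like and 0.20 in Th1-like cells, a difference of -0.49. Mitochondrially encoded genes were at 0.47 and -0.35, a difference of 0.82. With TMM factors the Tfh-like value was 0.22, and the Th1-like value of -0.35 lay within the range of random lists (-0.39 to 0.21). Barcodes left out for having few genes, which entered only the alternatives with all barcodes, carried red cell genes in 92.6% of their UMIs on day 7 (2 barcodes) and 92.8% on day 14 (12 barcodes).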

How the results depend on the processing

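No paired analysis was possible because each day is 1 library, and the shared replicate number 1 pairs nothing. The tests in T cell clusters, with the T cells of the mixed haemoglobin-led cluster put back, at matched depth before clustering, in the shared Tfh-like cluster and with scaling inside a class were chosen only after the results were seen. The Il21 ratio was 0.06 to 0.49 under 12 alternatives. Its interval included 0 with all barcodes, the stricter cell filter, deep cells left out, TMM, DESeq2, ribosomal and mitochondrial genes left out, thinning, and the cycling cluster left out, and in T cell clusters with the stricter filter and deep cells left out. Glycolysis stayed lower under all 14 (-1.09 to -0.83). Of the main values 110 stayed within their counting interval, or within 1.5 times for a count, 77 moved beyond it and 1 turned. Of the other values 203 stayed, 124 moved and 11 turned. A change of sign was counted as turned only where the main interval excluded 0. Unless a value shows it, the cause was not tested. Counts below are genes at least 2-fold higher, then lower, on day 14, and medians are of lists over all cells.

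The main Tfh, Th1 and central-memory medians over all cells were -0.0145 (-0.13 to 0.07), -0.35 (-0.45 to -0.29) and 0.65 (0.53 to 0.84). With DESeq2 factors the counts were 245 and 352 and the Tfh, Th1 and central-memory medians -0.16, -0.49 and 0.51. TMM gave a Th1 median of -0.45. Cells thinned to 2000 UMIs gave 576 genes higher and a Th1 median of -0.0686, no expression filter 1650 and 675, and a mean CPM of at least 50 gave 79 and 70, as fewer genes entered. The stricter cell filter gave Tfh and Th1 medians of -0.23 and -0.27, per-cell means -0.17 and -0.19 with a central-memory median of 0.52, and cells above 2 times the median UMIs left out a Th1 median of -0.28. Without the cycling cluster the Tfh median was -0.21. Without clusters of other cell types the Tfh and Th1 medians were 0.0860 and -0.25, and with the T cells of the mixed cluster put back 0.17 and -0.15, with a central-memory median of 0.87. Among lists whose main interval excluded 0, medians that turned were interferon-stimulated genes (-0.0486 without deep cells, -0.0464 with per-cell means, -0.15 thinned), red cell genes (-0.91 without deep cells), inhibitory receptors (0.0233 without ribosomal and mitochondrial genes, 0.0780 thinned, 0.0841 without the expression filter, 0.18 at 50 CPM, 0.0613 with the T cells put back), cytotoxic genes (0.0773 without the filter) and G2/M genes (0.0828 without the cycling cluster). In T cell clusters the Tfh median of 0.09 became -0.03 with TMM, -0.07 with DESeq2, -0.05 with per-cell means, -0.11 thinned and -0.01 without the cycling cluster. There the ribosomal median turned to 0.00549 under the stricter cell filter and the cytotoxic one to 0.0585 without the expression filter.

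Class shares also moved. Resolution 0.4 gave 12.9% Tfh-like and 54.6% central-memory-like on day 14, cycling shares of 18.8% and 8.39%, and 1.06% and 1.96% of other cell types. Resolution 1.2 gave Tfh-like 20.6% and 30.2% and central-memory-like 12.1% and 24.3% on day 7 and day 14, with 67 cells left without a class and 48 in interferon-stimulated clusters. With 1000 variable genes the day 14 shares were 19.8% and 32.1%. Centring genes within libraries gave 44.0% Tfh-like on day 7 and 35% central-memory-like on day 14. Without cell cycle genes Tfh-like cells were 17.4% and 10.2%, with 107 cells left without a class. Each library clustered alone gave Tfh-like 17.7% and 32.0%, central-memory-like 23.8% and 22.5%, and 0% Th1-like on day 7, where 33.0% were named as other cell types and 25.5% as cycling. Calls from marker UMIs gave Tfh-like 42.9% and 31.4%, Th1-like 34.4% and 27.4%, and central-memory-like 22.7% and 41.2%. They put every cell into the Tfh-like, Th1-like or central-memory-like class, also cycling cells and cells of other types. In these calls 20 of 282 and 52 of 548 cells had their best classes within 10% of each other. All barcodes gave Tfh-like 36.5% and 10.3% and 32.6% central-memory-like on day 14. Without Scrublet calls the latter was 31.1%, and over T cell clusters 45.0%. Thinning before clustering gave central-memory-like 12.4% and 53.8% and 13.0% Tfh-like on day 14, with cycling shares of 16.7% and 6.02%.

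Within Tfh-like cells, TMM gave 266 and 271 genes and DESeq2 266 and 272. The shared cluster gave 1100 and 365, where counting noise alone gave 420 and 446. Resolution 0.4 gave 828 higher and resolution 1.2 gave 213 lower. The planned receptor segment result gave no value under any setting. Within Th1-like cells the counts stayed within 1.5 times under both scalings and resolutions. The share of cells with an Il21 UMI was 4.61% and 7.32% at 1000 UMIs, 17.5% and 16.4% at 3000, and 39.7% and 25.7% without thinning, where depth sets the level. For cells with against without Il21, 1000 UMIs gave a Tfh list value of 0.0803 (-0.40 to 0.53) on day 7 and Th1 values of -1.13 and -1.07. Tfh-like cells alone gave 0.31 and -0.12 for the Tfh list and -0.27 and -0.46 for the Th1 list, and T cell clusters a day 14 Th1 value of -1.09. At least 5 G2/M UMIs gave 39.4% and 22.1%.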

Other observations

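The tests of a shift of the whole day 14 library, of free RNA and of joint capture were chosen only after the result was seen. The planned use of antigen receptor segments gave no value, since the gene names hold none. In T cell clusters, 6 of 22 genes of cytokine receptors and STAT signalling were at least 1.5-fold higher on day 14, 0 lower and 16 within 1.5-fold (median 0.40, 0.28 to 0.49, and 0.24 with DESeq2 factors). Cish and Socs1, which STAT proteins induce and which dampen cytokine signals, were at 2.00 (1.34 to 2.71) and 1.16 (0.90 to 1.43), and Il21r at 0.67 (0.40 to 0.94). Among 5 measured genes of regulatory and Tr1 cells 3 were higher (median 0.63, 0.47 to 0.78), with Nrp1 at 0.81 and Ikzf2 at 0.63. Cytotoxic genes went both ways (5 of 13 higher, 4 lower, with a median of -0.80 to 0.06 under the alternatives): Gzma, a granzyme, was at 3.97 (3.33 to 4.69) and Gzmk at 2.23 (1.53 to 3), and Serpinb6b was at -1.57. Survival genes also went both ways (4 of 17 higher, 4 lower): the pro-death genes Bcl2l11 and Bbc3 were at -1.69 and -1.50.

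Interferon-stimulated genes in T cell clusters had a median of 0.17 (0.11 to 0.29), with 8 of 36 higher and Ifi44 at 2.55 (1.74 to 3.46). That median lay within the range of random lists (-0.20 to 0.19) and was 0.05 with TMM factors, 0.01 with DESeq2 factors and 0.04 with cells thinned. Stress genes had a median of 0.48 (0.35 to 0.56), with 8 of 16 at least 1.5-fold higher, among them the early genes Fosb (1.21) and Junb (0.87), and 1 lower, the heat shock gene Hsp90ab1 (-0.60). Antigen receptor induced genes were at 0.11 (-0.02 to 0.21), which TMM and DESeq2 factors turned to just below 0. General T cell genes were at 0.31 (0.24 to 0.36), with Cd4 at 0.64. Among markers of other cells in T cell clusters, B cell genes were at 2.05 (1.75 to 2.55, 4 measured), myeloid genes at 0.99 (0.68 to 1.58) and red cell genes at 3.77 (3.55 to 4.01). The B cell list is not specific to B cells. It holds H2-Ab1 and H2-Eb1, which also marked a cluster led by the macrophage genes C1qa, C1qb and C1qc. Of the NK list 1 gene was measured, Tyrobp at 2.71, which myeloid cells also express, and of the CD8 list Cd8b1 at -0.30 (-0.96 to 0.34). Ctse had 21.3 UMIs per 100 Hbb-bs UMIs in day 14 T cell clusters and 0.452 in 18 red cells, a comparison made after the values were seen.

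The central-memory-like share was 34.0 points higher on day 14 with both libraries clustered together, and lower depth on day 14 could not account for it, since thinning every cell to 2000 UMIs first gave a difference of 41.4 points. With genes centred within libraries it was 26.5 points, yet with each library clustered alone it was -1.26 points. The bound set for the centred value alone would have excluded a shift of the whole library, and the reading was widened after the values were seen, because clustering alone removed the difference. That setting names classes against each library's own mean and put 33.0% of day 7 cells among other cell types, so its value does not settle the matter either way. Calls from marker UMIs gave 22.7% on day 7 and 41.2% on day 14. Their scores were scaled by means over both libraries, so a library-wide shift would move these calls too. The central-memory median was 0.30 (0.10 to 0.41) in Tfh-like and -0.006 (-0.35 to 0.36) in Th1-like cells. Cells were put into classes partly by these genes, so these medians do not decide it. A library-wide shift and a larger share of such cells therefore cannot be told apart here, and the change of time itself stays open as an untested explanation.

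Glycolysis genes were lower on day 14. Fewer cells in the cycling cluster or with at least 3 G2/M UMIs could not be the whole cause. The other 94 and 212 T cells gave -0.80 (-0.97 to -0.65). That cut does not remove every dividing cell, such as those in S phase, so fewer dividing cells in general are not excluded. A shift of all abundant transcripts would leave the list among random lists matched on expression, and it lay at percentile 0. A different mix of classes cannot be told apart from a change within cells: the class nearer to 0 gave -0.52 (-0.62 to -0.40), whose interval crosses the bound of -0.5, and central-memory-like cells were too few on day 7 to compare. TMM factors gave -0.77 in Tfh-like and -1.04 in Th1-like cells, beyond that bound. The Tfh-like cluster shared by both days gave -0.38 (-0.49 to -0.13) without such factors, which is not beyond it. The time after infection stays open and untested.

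A cluster of 24 day 14 cells carried the macrophage genes C1qa, C1qb, C1qc and Apoe, and 17 of them had at least 10 UMIs of Cd3 and Cd4 genes, although the sort was for CD4+ T cells. Free RNA spread evenly could not give it, since 18 cells had at least 5 C1q UMIs where 3.75 were predicted. A T cell and a macrophage, or a piece of one, may have been captured together, but the cluster's median of 6290.5 UMIs was 1.11 times the 5660 of T cell clusters, between the bounds set for and against, so this cannot be told apart from T cells carrying such RNA. No biological explanation was tested.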
